A study of Mus musculus with 10 samples.

How the data were processed

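Total RNA from bone marrow-derived macrophages of mice was labelled and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, which measure transcripts with sets of short oligonucleotide probes. Macrophages had been grown from marrow with macrophage colony-stimulating factor. The 10 arrays fell into 4 groups by their labels. Wild type cells without LPS and Atf3-/- cells without LPS had 3 arrays each, and wild type cells with LPS and Atf3-/- cells with LPS had 2 arrays each. LPS was given at 10 ng/mL for 4 h. Nothing in the labels states whether arrays of a group came from separate mice or cultures, so p-values measure only the spread between these arrays, which may be technical.

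The values used were the deposited log2 expression values, 1 per gene-level probeset and array. Per the series' design text, the arrays had first been released with an earlier study and the authors re-processed the probe intensities with CustomCDF probesets of version 13, which regroup the probes by Ensembl gene. The tool affy 1.26.1 is named in the submitters' processing notes. The background correction, the normalization between arrays and the way probes were summarised are not given in the sources used here. Differences therefore rest on whatever normalization the submitters applied. The table held 16860 probesets with 0 missing cells and 0 control probesets. The arrays' medians ranged from 5.45 to 5.56 on the log2 scale, and their lowest values from 2.26 to 2.41. Values near that lower end carry background signal, so folds measured from there depend on the background correction. No depth applies to arrays, and the number of arrays limits the precision.

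Rows were named by Ensembl mouse gene ID. The files do not pair these IDs with gene names, and 0 of the 16860 matched an entry of the reference table used. The level of Atf3 in each array was therefore not analysed here, and the genotype labels rest on no check of the targeted gene. The 25 gene lists fixed in advance and a test of positions around Atf3 were not run for the same reason. The rule for named genes took, for each comparison, genes past the threshold with the largest increases and decreases, provided that the arrays of the groups compared did not overlap. For the response difference it asked only for the threshold. That rule asked for gene symbols. Without them it was applied to IDs, limited to 2 that were higher and 2 that were lower per comparison. This change was made after the table had been read.

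All 10 arrays were fitted together with 1 mean per group using limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 6 residual degrees of freedom and a prior of 5.44 degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all 16860 probesets of a contrast and a threshold of 0.05. The 5 contrasts were LPS in wild type, LPS in Atf3-/-, the difference between these responses, and Atf3-/- minus wild type without and with LPS. All adjusted p-values in the text come from limma with this adjustment. Genes past the threshold and at least 2-fold up or down in the mean LPS response of both genotypes formed the LPS-induced and LPS-repressed sets. With equal numbers of arrays per genotype and treatment, this mean response is independent of the genotype contrasts by design. In the alternative fits the shares of these sets were taken over sets formed anew in each fit. With an array left out, or with the covariate described below, that independence need not hold. The position of an array along the mean LPS response was its projection on that response across all genes, scaled so that the mean without LPS was 0 and the mean with LPS was 1. Positions were compared with two-sided exact permutation tests.

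The fit was tested on simulated data in which 200 of the 16860 genes were changed by known amounts, in 5 runs. At a log2 difference of 1 the fit recovered 89.6% of changed genes for LPS in wild type and 88.8% for LPS in Atf3-/-. It recovered 63.2% for the response difference, 92.8% for the genotype difference without LPS and 80.0% for that with LPS. At a log2 difference of 0.5 the response difference was recovered for 8.0% of changed genes. With the covariate described below, recovery at a log2 difference of 1 was 61.6% for LPS in wild type and 82.4% for LPS in Atf3-/-. It was 40% for the response difference, 80.4% for the genotype difference without LPS and 71.6% with LPS. Recovery depends on the share of genes changed, so these rates need not hold for the real contrasts.

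The groups, tests, sets and most alternatives were fixed before the data were examined. Those alternatives were the replicate number as a block, quantile normalization, subtraction of each array's median, and a filter at the 40th percentile of mean expression. They also included a trended robust prior, array weights, fits of only the compared arrays, a 2-fold minimum, limma's treat at 1.5-fold, and leaving out each array in turn. Where an omission left 1 array in a group, that array was assumed to vary like those of the other groups. A division of the arrays by 4 probesets that were either high or low was noticed in the data, and fits with this division as a covariate, with 5 residual degrees of freedom, were added afterwards. So were fits of the arrays of 1 state alone, in which some groups held 1 array under the same assumption, all alternatives for the positions and for shares of gene sets without LPS, and a few others named in the closing section. A probeset counted towards the division if its values left a gap of at least 1.5 on the log2 scale that was wider than the range on either side. Each side also had to hold at least 2 arrays, and the gap had to fall within a group. This rule was written after the values had been seen.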

Results

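Gene expression was measured in bone marrow-derived macrophages of wild type and Atf3-/- mice, on a C57BL/6J background per the labels, with and without LPS at 10 ng/mL for 4 h. LPS is a component of the outer membrane of Gram-negative bacteria that activates macrophages through Toll-like receptors. ATF3 is a transcription factor of the ATF/CREB family that is induced by Toll-like receptor signals and is known to restrain inflammatory genes. The design asks how macrophages responded to LPS, how far that response depended on Atf3, and how the genotypes differed in either state. Without LPS there were 3 arrays per genotype, and with LPS 2 arrays per genotype. Each of the 16860 probesets stood for 1 Ensembl gene and is called a gene here, identified by its ID because the files do not pair IDs with names.

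LPS was the main source of variation among the arrays. The first principal component held 80.5% of the variance and separated the arrays with LPS from those without. The second component held 7.55% and separated the genotypes in both states. Arrays of the same group correlated across genes at 0.991 to 0.996. Arrays of the same treatment but different genotype correlated at 0.982 to 0.991, and arrays of different treatment at 0.909 to 0.942. No arrays held identical values.

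The arrays also fell into 2 states that cut across the groups. In 4 probesets, picked out after their values were seen, each array was either high or low with no value between. ENSMUSG00000086503 lay at 8.95 to 9.57 on the log2 scale in 5 arrays and at 2.94 to 3.76 in the other 5. ENSMUSG00000069045, ENSMUSG00000068457 and ENSMUSG00000069049 showed the opposite pattern in the same arrays, for example 8.29 to 8.71 against 2.94 to 3.26 for the first of these. The state with high ENSMUSG00000086503 held all 3 wild type arrays without LPS and 0 of the 2 wild type arrays with LPS. It held 1 of 3 Atf3-/- arrays without LPS and 1 of 2 with LPS. In wild type the states thus coincided with treatment. For each comparison below that uses wild type arrays, the number of genes called is also given with the state as a covariate. In that fit the effect of the state is estimated from the Atf3-/- arrays alone. It is assumed to be the same in wild type, and the same with and without LPS. The wild type arrays themselves cannot separate the state from LPS.

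**Figure D1:**
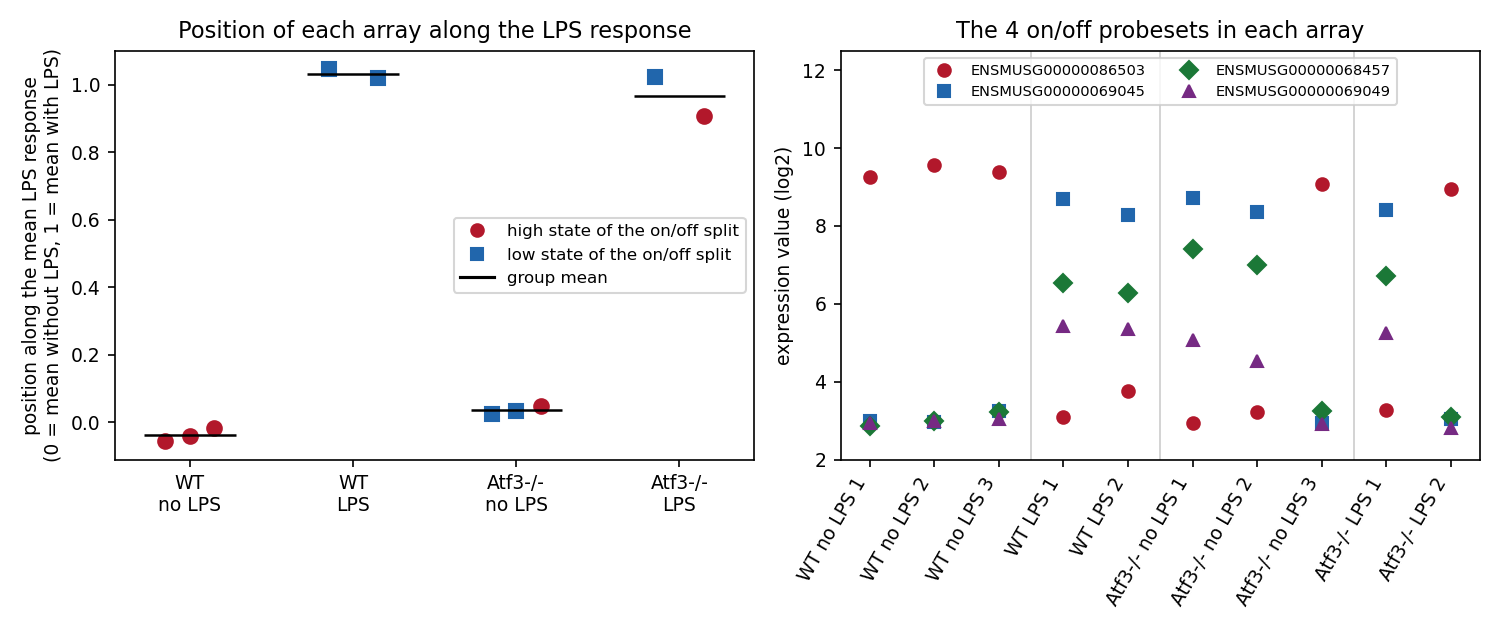
Left, position of each array along the mean LPS response, where 0 is the mean without LPS and 1 the mean with LPS, with lines at group means and symbols for the 2 states of the on/off probesets. Right, log2 values of the 4 on/off probesets in each array, in which ENSMUSG00000086503 is high in the 5 arrays where the other 3 are low.

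In wild type macrophages LPS changed the expression of 6967 genes, 41.3% of those measured, with 3004 higher and 3963 lower, or 3591 and 3653 after each array's median was subtracted. Induction reached larger sizes than repression. Among the genes that changed, 109 rose at least 16-fold and 33 at least 64-fold, while 13 fell at least 16-fold and 0 at least 64-fold. On/off probesets were not removed from these counts. The 13 include ENSMUSG00000086503, whose difference in wild type cannot be separated from the state of the arrays. ENSMUSG00000025746 rose from 2.86 ± 0.11 (SD, n = 3) to 12.02 ± 0.13 (SD, n = 2) on the log2 scale (log2 difference 9.16, SE 0.10, limma adjusted p = 2.56e-13). ENSMUSG00000032487 rose from 3.23 ± 0.09 (SD, n = 3), with a log2 difference of 9.07 (SE 0.11, adjusted p = 2.90e-13). Both started near the lower end of the arrays' range, so these differences depend on the background correction. ENSMUSG00000051495 fell from 10.48 ± 0.14 (SD, n = 3) to 5.51 ± 0.22 (SD, n = 2), a log2 difference of -4.97 (SE 0.15, adjusted p = 2.82e-10). The largest fitted decrease, -5.98 (SE 1.72, adjusted p = 0.0147), belonged to the on/off probeset ENSMUSG00000086503 and was -0.12 (adjusted p = 0.799) with the state in the fit. A value near 0 was fixed in advance there, since the state was set by this probeset's own values. The decrease also missed the threshold without either wild type LPS array (-5.64 and -6.31) and with a trended robust prior.

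The median absolute log2 difference of the genes called in wild type was 0.72, and 2328 changed at least 2-fold, 1072 up and 1256 down. With the state as a covariate 4797 genes were called, 1992 higher and 2805 lower, of which 4613 were called in both fits. The standard errors of this contrast were at the median 1.45 times as large in that fit.

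In Atf3-/- macrophages LPS changed 6931 genes, 2784 higher and 4147 lower, with 1886 changed at least 2-fold (852 up, 1034 down). Strong induction was found for fewer genes than in wild type. At least 16-fold increases were found for 73 genes and at least 64-fold increases for 18, a difference in counts that was not itself tested. The genes with the largest increases were ENSMUSG00000025746 (log2 difference 9.83, SE 0.10, adjusted p = 1.15e-13) and ENSMUSG00000032487 (log2 difference 8.88, SE 0.11, adjusted p = 4.49e-13). ENSMUSG00000063193 fell from 11.09 ± 0.10 (SD, n = 3) to 5.38 ± 0.18 (SD, n = 2), a log2 difference of -5.71 (SE 0.11, adjusted p = 1.53e-11). ENSMUSG00000038332 fell by 5.40 on the log2 scale (SE 0.13, adjusted p = 1.08e-10). The division into higher and lower genes depended on scaling, since subtracting each array's median gave 3761 higher and 3718 lower, with the median of all genes at 0.11. With the state as a covariate 6827 genes were called, 6584 of them in both fits.

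The responses of the genotypes had the same direction for nearly all genes called in both. Of 4972 such genes 98.7% had the same sign, with 1821 higher and 3087 lower in both genotypes, where independent lists would share 496 and 975. These comparisons share no array. Across all genes the responses correlated at r = 0.896, with genes not being independent replicates. The slope through the origin of the Atf3-/- response on the wild type response was 0.785, and that of the wild type response on the Atf3-/- response was 1.02. Noise in the horizontal variable lowers each slope. Without Atf3-/- LPS replicate 2 the first slope was 0.842 and the second 0.970.

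The size of the LPS response differed between genotypes for 1005 genes, 402 with a response difference (Atf3-/- minus wild type) above 0 and 603 below 0. In 529 of them the response had the same direction in both genotypes and was smaller in Atf3-/-, and in 162 it was larger in Atf3-/-. The fitted directions were opposite in 314, of which 64 passed the threshold in both genotypes. Among the 940 LPS-induced genes the response difference was below 0 in 201 called genes and above 0 in 30, with a median of -0.38 on the log2 scale over all 940. Among the 1081 LPS-repressed genes 142 called genes lay above 0 and 43 below 0, with a median of 0.22.

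ENSMUSG00000024675 rose by 6.92 on the log2 scale in wild type and by 3.76 in Atf3-/- (response difference -3.16, SE 0.28, limma adjusted p = 8.16e-04). Its level without LPS was 4.22 ± 0.08 (SD, n = 3) in wild type and 7.21 ± 0.30 (SD, n = 3) in Atf3-/-. ENSMUSG00000018500 rose by 3.81 in wild type and by 0.81 in Atf3-/- (response difference -3.00, SE 0.37, adjusted p = 0.00230). In ENSMUSG00000048806 the wild type response was 0.25 (adjusted p = 0.654), while the gene rose by 3.20 in Atf3-/- (response difference 2.96, SE 0.55, adjusted p = 0.0121). Its 2 Atf3-/- arrays with LPS lay far apart, at 7.46 ± 1.31 (SD, n = 2). The response difference was 3.88 without replicate 1 of these arrays and 2.03 without replicate 2. ENSMUSG00000038508 fell by 3.22 in wild type, against -0.73 (adjusted p = 0.0505) in Atf3-/- (response difference 2.49, SE 0.39, adjusted p = 0.00584). The last 2 genes missed the threshold with the state as a covariate, at 2.08 (adjusted p = 0.150) and 2.03 (adjusted p = 0.0799). ENSMUSG00000048806 also missed it without wild type LPS replicate 1, at 2.93.

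With the state in the fit 133 response differences were called, 36 above 0 and 97 below 0, of which 121 were called in both fits. Of these 133 the response was smaller in Atf3-/- in the same direction in 81, larger in 13 and opposite in 39. Called induced genes then numbered 50 below 0 and 4 above, and called repressed genes 11 above and 4 below. The standard errors were at the median 1.33 times as large, and the fitted differences of the genes called at first had a median ratio of 0.929 to their former size. Under quantile normalization 1026 genes were called and the directions were near balance, with 520 above 0 and 506 below 0. The count was 290 without wild type LPS replicate 1, 500 without Atf3-/- LPS replicate 2, 524 and 617 without Atf3-/- unstimulated replicates 2 and 3, and 571 without wild type unstimulated replicate 1.

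**Figure D2:**
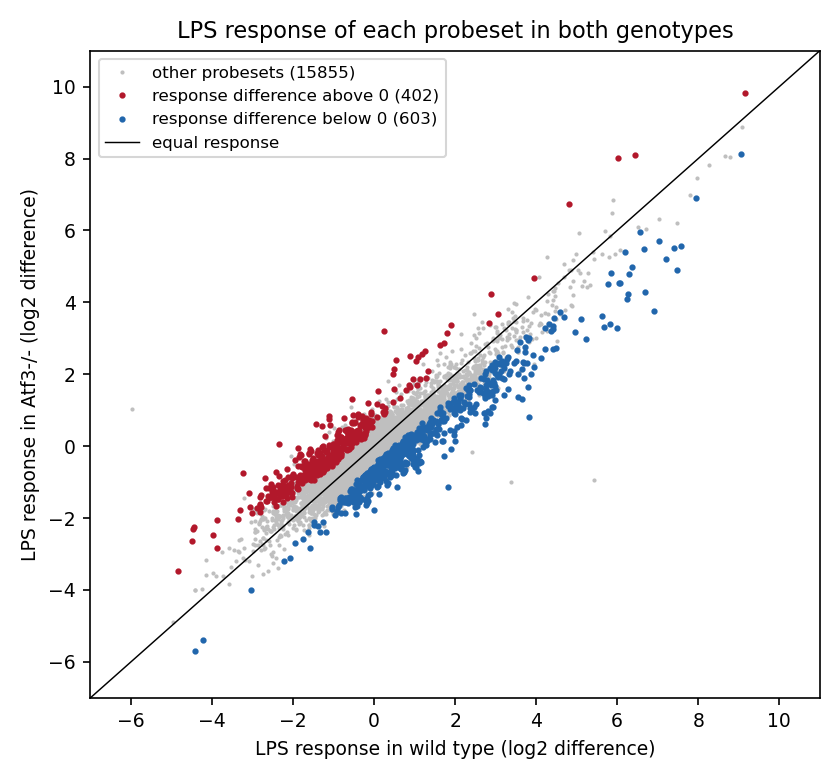
Log2 difference between LPS and no LPS in wild type (horizontal) and in Atf3-/- (vertical) for each of the 16860 genes, with the 402 and 603 genes whose response difference lay above and below 0 in colour and a line at equal response. The responses correlate at r = 0.896 across genes.

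Without LPS 2157 genes differed between the genotypes, 1208 higher and 949 lower in Atf3-/-, a balance that turned to 994 higher and 1103 lower under quantile normalization. Most differences were modest, with a median absolute log2 difference of 0.53, and 206 genes differed at least 2-fold (133 higher, 73 lower). Genes induced by LPS were more often higher than lower in unstimulated Atf3-/- cells. Of the 940 LPS-induced genes 69.7% had a higher mean in Atf3-/- without LPS, with 236 called higher and 37 called lower and a median difference of 0.18. Of the 1081 LPS-repressed genes 45.3% were higher, with 114 called higher and 185 called lower. With the state as a covariate, and the sets formed anew in that fit, the shares were 50.0% for repressed and 65.8% for induced genes. Of the 1081 repressed genes 81 were then called higher and 72 lower. Of the 940 induced genes 146 were called higher and 25 lower.

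ENSMUSG00000029322 had a level of 3.64 ± 0.34 (SD, n = 3) in wild type and 7.58 ± 0.28 (SD, n = 3) in Atf3-/- (log2 difference 3.94, SE 0.20, limma adjusted p = 8.38e-07). ENSMUSG00000034438 lay at 3.01 ± 0.19 (SD, n = 3) in wild type and 6.46 ± 0.14 (SD, n = 3) in Atf3-/- (log2 difference 3.44, SE 0.12, adjusted p = 5.02e-08). The wild type levels of both were near the lower end of the arrays' range, where background signal can lessen a difference. Both also rose with LPS in wild type, by 2.73 and 2.28 on the log2 scale. ENSMUSG00000056071 had a level of 8.45 ± 0.14 (SD, n = 3) in wild type and 4.42 ± 0.14 (SD, n = 3) in Atf3-/-, a log2 difference of -4.02 (SE 0.11, adjusted p = 4.37e-09). ENSMUSG00000056054 was lower in Atf3-/- by a log2 difference of -3.97 (SE 0.16, adjusted p = 1.10e-07).

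Along the mean LPS response the wild type arrays without LPS lay at -0.0368 ± 0.0197 (SD, n = 3) and the Atf3-/- arrays at 0.0368 ± 0.0120 (SD, n = 3). The groups did not overlap, and the exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow, so that a p under 0.05 was out of reach. With the state in the fit 1052 genes were called, 650 higher and 402 lower, of which 929 were called in both fits. The count was 1193 and 1336 without Atf3-/- unstimulated replicates 2 and 3, and 1382 and 1321 without wild type unstimulated replicates 1 and 3.

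After LPS 662 genes differed between the genotypes, 331 in each direction, with 201 at least 2-fold apart (111 higher and 90 lower in Atf3-/-). LPS-induced genes were more often lower in Atf3-/- after LPS, with 118 called lower and 56 called higher. LPS-repressed genes were more often higher, with 106 called higher and 22 called lower. Over the whole sets 33.8% of induced and 67.1% of repressed genes had a higher mean in Atf3-/-. Without Atf3-/- LPS replicate 2 these shares were 46.5% and 50.6%. With the state as a covariate they were 37.0% and 62.2%. Both pairs of shares are over sets formed anew in the fit. Within the sets as first formed, the fit with the state called 79 induced genes lower and 42 higher. It called 47 repressed genes higher and 20 lower.

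ENSMUSG00000038508 had a level of 6.51 ± 0.19 (SD, n = 2) in wild type and 9.51 ± 0.90 (SD, n = 2) in Atf3-/- after LPS (log2 difference 3.00, SE 0.30, limma adjusted p = 2.88e-04). ENSMUSG00000040950 was higher in Atf3-/- by 2.93 on the log2 scale (SE 0.43, adjusted p = 0.00299). ENSMUSG00000056071, lower in Atf3-/- without LPS, was also lower after LPS, at 8.00 ± 0.13 (SD, n = 2) against 4.60 ± 0.04 (SD, n = 2), a log2 difference of -3.41 (SE 0.13, adjusted p = 2.83e-07). ENSMUSG00000072844 differed by -3.32 (SE 0.24, adjusted p = 3.61e-05).

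Along the mean response the arrays after LPS lay at 1.03 ± 0.02 (SD, n = 2) in wild type and 0.967 ± 0.081 (SD, n = 2) in Atf3-/-, where replicate 2 lay at 0.909 (exact permutation p = 0.667, smallest possible 0.333). With the state in the fit 419 genes were called, 190 higher and 229 lower, of which 376 were called in both fits. The count was 231 without wild type LPS replicate 1, 319 without Atf3-/- LPS replicate 2, 414 with array weights, and 63 when the fit used only the 4 arrays compared.

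Part of the genotype difference was shared between the states. Of the genes called without LPS 214 were also called after LPS, with 114 higher and 58 lower in Atf3-/- in both, where independent lists would share 23.7 and 18.6. Another 28 were higher without LPS and lower after it, and 14 were lower and then higher. These comparisons share no array. The genes called in both states with the same direction made up 7.97% of those called without LPS.

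**Figure D3:**
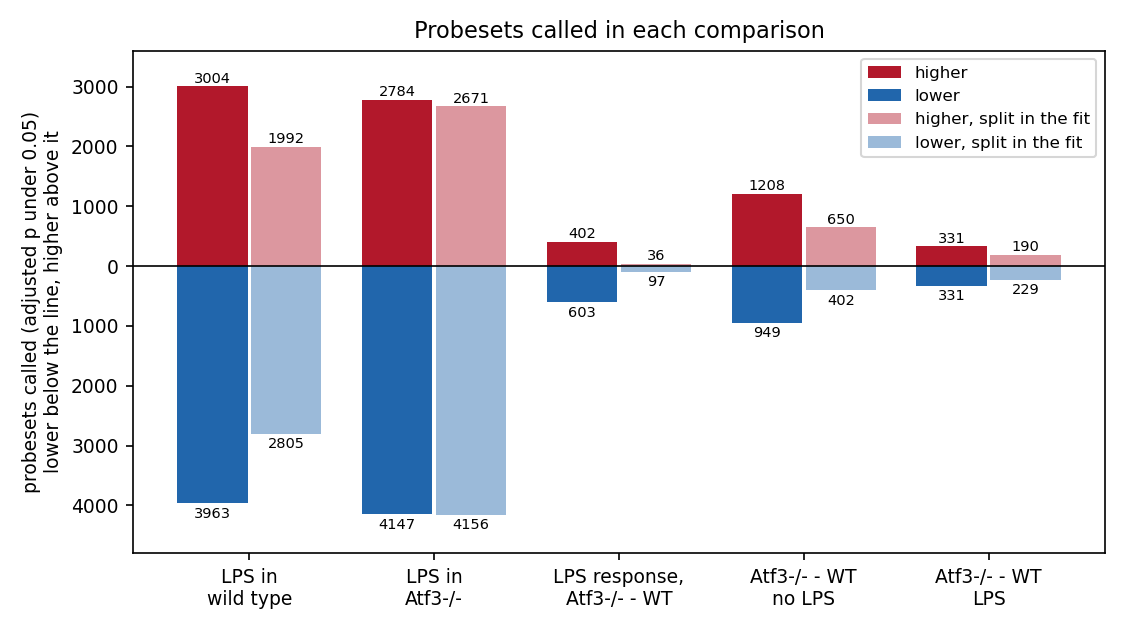
Number of genes past an adjusted p of 0.05 in each of the 5 comparisons, with higher genes above the line and lower genes below it. Dark bars are the fit by group and pale bars the fit with the state of the on/off probesets as a covariate, in which the response difference between genotypes falls from 402 and 603 genes to 36 and 97.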

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

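The tests of array scaling, of a single weak array and of the on/off division of the arrays were chosen after the result was seen. The LPS response differed between the genotypes for 1005 genes by limma's test of the difference itself, with 402 response differences above 0 and 603 below 0. Under quantile normalization 520 lay above 0 and 506 below, and with the state in the fit 36 and 97. Among the genes named in the report, the response difference passed limma's test in the main fit for ENSMUSG00000025746 (0.66), ENSMUSG00000048806 (2.96), ENSMUSG00000038508 (2.49) and ENSMUSG00000056054 (1.16). It also passed, below 0, for ENSMUSG00000024675 (-3.16), ENSMUSG00000018500 (-3.00), ENSMUSG00000029322 (-1.79), ENSMUSG00000034438 (-1.56), ENSMUSG00000063193 (-1.30) and ENSMUSG00000038332 (-1.18). The last pair fell further with LPS in Atf3-/- than in wild type. Levels without LPS lay near the lower end of the arrays' range for ENSMUSG00000025746 in both genotypes. The same held for ENSMUSG00000029322 and ENSMUSG00000034438 in wild type. The response differences of these genes therefore depend on the background correction. The count was 290 without wild type LPS replicate 1, 500 without Atf3-/- LPS replicate 2, 524 and 617 without Atf3-/- unstimulated replicates 2 and 3, and 571 without wild type unstimulated replicate 1.

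Across all genes the response difference had a slope of -0.140 on the mean LPS response, made up of a genotype difference of -0.0665 after LPS minus one of 0.0735 without LPS. Scaling of the arrays as the whole cause was argued against by a slope of -0.150 after quantile normalization. A single weak LPS array concerns by construction only the part after LPS, for which it could account, since that part was -0.00295 without Atf3-/- LPS replicate 2 (slope -0.0740). The on/off division may also contribute to the part after LPS, -0.0501 with it in the fit against a spread of 0.0589. Atf3-/- LPS replicate 2 was also the only Atf3-/- LPS array of the high state. The weak array and the division therefore cannot be told apart there. With the division in the fit the part without LPS was 0.0597, where the state is taken to act alike with and without LPS. An effect of the genotype stays open, and after LPS, with 2 arrays per genotype, it cannot be told apart from a weak array, since leaving out the lower of 2 arrays always raises their mean.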

How the results depend on the processing

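The fits with the on/off state of the arrays, the fits of 1 state alone, and all alternatives for the positions and the shares without LPS were chosen after the data were seen. So were array weights and the trended robust prior for the other shares and the comparison of responses, and array weights and the dim filter for named IDs. Counts of called genes stayed within 1.5 times the reported ones under quantile normalization, median subtraction, the filter on dim probesets, the trended robust prior and the replicate block, and under array weights except after LPS (414 against 662). The count for LPS in wild type was 5862 to 7067 with 1 array left out, and in Atf3-/- 5063 to 6994. For the response difference the range was 290 (without wild type LPS replicate 1) to 1364, with 500, 524, 617 and 571 without Atf3-/- LPS replicate 2, Atf3-/- unstimulated replicates 2 and 3 and wild type unstimulated replicate 1, for the genotype difference without LPS 1193 (without Atf3-/- unstimulated replicate 2) to 2418, with 1336, 1382 and 1321 without Atf3-/- unstimulated replicate 3 and wild type unstimulated replicates 1 and 3, and after LPS 231 (without wild type LPS replicate 1) to 971, with 319 without Atf3-/- LPS replicate 2. With a 2-fold minimum the counts were 2328 and 1886 for LPS in wild type and Atf3-/-, 383 for the response difference, and 206 and 201 for the genotype without and after LPS, and with treat at 1.5-fold they were 2384, 1819, 21, 95 and 59, lower by construction. With the state as a covariate the last 3 comparisons gave 133, 1052 and 419. Over the 5 other divisions of the same shape they gave 42 to 733, 787 to 1401 and 306 to 768, ranges that include the values with the real state. Arrays of the high state alone gave 3328 genes for LPS in Atf3-/- (1 array against 1) and 497 for the genotype without LPS (1 against 3). Arrays of the low state alone gave 4837 for LPS in Atf3-/- (1 against 2) and 169 for the genotype after LPS (1 against 2). In each, the lone array was assumed to vary like the other groups, so these counts say little about stability. Only the compared arrays gave 63 after LPS. The fit for the response difference uses all arrays and has no such alternative.

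The correlation of the responses was 0.913 with the dim filter and 0.859 to 0.904 with 1 array left out. The slope on the wild type response was 0.727 to 0.842, and that on the Atf3-/- response 0.970 to 1.04, with 1.05 under the dim filter and 0.988 with the state in the fit. The share with the same sign was 98.3% to 99.1%, and 98.3% with the replicate block. With 1 array left out, the share higher in Atf3-/- after LPS was 28.7% to 46.5% for induced genes and 50.6% to 71.3% for repressed genes, both nearest 50 without Atf3-/- LPS replicate 2. Without LPS the share of induced genes was 68.4% to 70.6%, and 66.7%, 67.8%, 71.0% and 65.8% under quantile normalization, median subtraction, the dim filter and the state. That of repressed genes, 45.3% as reported, was 42.2% to 49.6%, 42.1% under quantile normalization, and turned to 50.05% with the state. The induced and repressed sets were formed anew in each of these fits. The position difference after LPS was -0.104 to -0.00295 and the slope of the response difference -0.179 to -0.0740, both smallest in size without Atf3-/- LPS replicate 2. Apart from changes explained by fewer arrays or genes, the cause was not tested. For named IDs 333 alternatives kept direction and call. Another 7 kept direction and lost the call, 4 of them for ENSMUSG00000086503, including the fit with the state, which its own values define.

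The replicate numbers did not meet the rule for pairing, a correlation over 0.1 in every same-numbered pair. Deviations of same-numbered arrays from their group means correlated at -0.0651 to 0.299 over 13 pairs, with 7 over 0.1, against -0.281 to 0.238 over 24 other pairs with 4 over 0.1, and 3 of 6 unstimulated arrays correlated best with their own number. A partial batch by number stays open. With the replicate block the counts were 7256, 7534, 1278, 2556 and 806 in the order given above. Not run for want of gene names were the gene lists, the position test and their alternatives. The number of arrays limits the precision, and signal over background was not analysed here.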

Other observations

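Among the tests here, those of label exchange, donor sex, array scaling, uniform activation and the on/off division were chosen after the result was seen. Among the 1005 genes with a response difference, 550 also differed between genotypes only without LPS, 237 only after LPS, 57 in both states and 161 in neither. These counts share arrays with the response difference and are a description, not a separate test. The 90 genes induced at least 16-fold on average included 41 that were higher and 3 that were lower in Atf3-/- without LPS.

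The 4 on/off probesets had the largest spread within groups of all genes, from 0.957 to 2.59 on the log2 scale against a median of 0.137. In a fit with the state, 12 genes were called for it, these 4 included, and 0 for each of the 5 other divisions of the same shape. For these 4 both the spread and the call follow from the rule that picked them. Labels exchanged between groups are argued against, since all 10 arrays lay nearer to their own genotype in genes called on arrays of the other treatment, and to their own treatment. Donor mice of different sex are a candidate explanation, because sex-linked transcripts would be present or absent in this way, although the labels give female mice for all arrays. This stays open, because all 4 probesets lacked a name or position in the tables used.

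Unstimulated Atf3-/- arrays were shifted along the LPS response by 0.0735 against wild type, a pattern noticed in these data. Scaling as the cause is argued against by a shift of 0.0833 after quantile normalization. That shift was larger than the spread of 0.0163 between arrays. With the on/off division in the fit the shift was 0.0597, which cannot decide whether the division contributes. The fit takes the state to act alike in both genotypes and with and without LPS. Among Atf3-/- arrays, however, the high-state array lay above the others without LPS (0.0495 against 0.0256 and 0.0352). With LPS it lay below (0.909 against 1.02). Other divisions of the same shape gave shifts of 0.0436 to 0.115. A uniform low-level activation stays open. Of the 90 genes induced at least 16-fold 73.3% were higher in Atf3-/- (70.0% to 75.6% without single arrays) against 97.9% under a shift in proportion to the log2 response, but that proportion is assumed and 17 of the 90 lay below the 25th percentile in unstimulated wild type cells. An effect of the genotype on LPS-induced genes may also contribute and stays open, beside culture batches, which the labels do not give.

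For the genotype difference without LPS, 10 splits of the 6 unstimulated arrays into 3 and 3 are too few for a share under 0.05. The real split called 2157 genes and was the 1 split that reached that count, and the highest other split called 0. Each other split put arrays of both genotypes into both of its groups. Any difference that follows the genotypes, whatever its cause, then widened the spread within groups. The low counts of the other splits therefore cannot decide the cause of the difference. Without Atf3-/- unstimulated replicate 2 the real count was 1193, and it was 1336 without replicate 3, and 1382 and 1321 without wild type unstimulated replicates 1 and 3.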
